A study of Mus musculus with 6 samples.

How the data were processed

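Strand-specific, rRNA-depleted RNA libraries were made from adherent peritoneal cells of thioglycollate-primed Balb/c mice, per the labels' protocols: 2 mL of 3% broth 3 days before sampling, 0.2 mL of PBS or BSN-37 into the peritoneum, lavage after 12 h and adherence for 4 h. RNA of 6 mice was pooled per replicate, giving 3 pools per group. The design text describes microarrays, while the library protocol and the deposited values are those of sequencing, and the values were treated as sequencing. Groups and replicate numbers come from the labels. Of the 6 libraries no pair was closer than sampling noise (chi-square per degree of freedom 55.2 to 277), and each counted as 1 replicate.

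The deposited gene table holds, per the file headers, whole-number read counts and FPKM for each library and 46141 genes. The authors' genome build was GRCm38, per the submitters' processing notes. The aligner, the counter and its use of strand, the annotation release and the circular RNA caller are not given in the sources used here. The deposited gene table also holds other columns, in which the authors give a DESeq2 p-value and log2 fold change for part of the genes, per the file headers, with calls at p under 0.05 and 1.5-fold. The deposited circular RNA table holds junction read counts and a signal named SRPBM, per the labels, in which each library's count is divided by a constant of 16.3 to 19.7. That constant does not match a scaling by all mapped reads, so the scale of the signal is open and reads are given in its place. The authors' p-value and log2 fold change for each circular RNA come from DESeq2, per the file headers, with calls at 2-fold. The smallest junction count above 0 was 2. Group means in the deposited tables (4 columns) were not used. Loci listed with more than 1 host gene (30 of 1273) were used once.

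Gene classes and coordinates were taken from GENCODE M21 (GRCm38) by Ensembl ID, which matched 42456 of 43339 IDs, and 2802 gene models of the authors without an Ensembl ID were not assigned a class. The classes not described in the report (pseudogenes, other RNAs, new gene models and unmatched IDs; 770, 637, 600 and 106 tested) gave 0 genes with edgeR, with 50, 30, 22 and 5 at an unadjusted p under 0.05 and 0, 0, 2 and 0 called by DESeq2.

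The design fixed before the data were examined assumed FPKM and named limma, with edgeR in its place if the table held counts. It did, so edgeR 4.0.16 (R 4.3.3; TMM factors, glmQLFit and glmQLFTest, two-sided) is the main test, and limma 3.58.1 on log2(FPKM + 1) for coding and log2(FPKM + 0.1) for long non-coding genes and DESeq2 1.42.0 are alternatives. Coding genes with at least 1 FPKM and long non-coding genes with at least 0.5 FPKM in at least 3 of the 6 libraries were tested, each class adjusted by Benjamini-Hochberg on its own with a threshold of 0.05. Circular RNAs read in at least 3 libraries were tested on junction counts, with library sizes in proportion to the authors' SRPBM constants. All fits compared BSN-37 with PBS over the 6 libraries without covariates. The threshold of the design text (an unadjusted p under 0.05 and a mean ratio over 2) is given as a second count. Fold changes are BSN-37 over PBS. For circular RNAs with 0 reads in a group, a floor of 3 reads over the group gives a lower bound, which holds only where a 0 reflects counting error. Floors allow for counting error only, and not for the spread between pools. No molecular identifiers were used, so repeated reads of 1 molecule are not told apart.

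Gene lists, 36 in number and 1 of them of long non-coding RNAs, were written before the data were examined, for macrophage activation and metabolism, RNA quality and the other cell types of a peritoneal lavage. Lists with at least 5 tested members went through camera with a correlation of 0.01, and again with an estimated correlation and fry. The lists described member by member were chosen after their values were seen. Named genes follow a rule fixed in advance. It takes coding genes past the adjusted threshold with groups that do not overlap and at least 5 FPKM, filled up to 12 per direction by lowest p, and up to 4 members of lowest p from each described list. It adds a fixed set of activation genes, and the 5 long non-coding and 5 circular RNAs per direction of lowest p (predicted-gene and clone names left out of the long non-coding ones). Gm37094, which has such a name, Gm26917, Malat1, Neat1 and the abundant circular RNAs, and any gene named as lost or gained in the closing section, were chosen after their values were seen. Neither Ly6c2 nor the Ifi200, schlafen and immunoglobulin genes can be separated fully from close paralogs, whose shared reads were counted in a way not given in the sources used here.

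Each test was checked on simulated counts with known changes. In 9874 simulated coding genes, 18% of 50 genes changed 1.5-fold were recovered, 82% at 2-fold, 98% at 3-fold and 100% at 4-fold, with 9 false calls. In 719 simulated long non-coding genes, recovery was 8%, 40%, 72% and 84% of 25 at the same folds, with 2 false calls. In 168 simulated circular RNAs it was 10% of 20 at 4-fold and 30% at 16-fold, so most changes of that size would be missed there. All were simulated as independent, and many were changed at once, which makes the adjusted threshold easier to pass than with few changes. Recovery in the data can therefore be lower: Serpinb10 had an edgeR adjusted p of 0.278 at a log2 difference of 2.61. Of 100 null lists, 4 had a camera p under 0.05. The genes of these lists were simulated as independent, so the check does not cover lists whose genes vary together. In the data the estimated correlation ran from -0.03 (apoptosis and p53 targets) to 0.95 (mitochondrial genome) over the tested lists. The alternatives covered filters, pseudocounts, scaling, the tool, library weights, a replicate block and leaving out each library in turn. With 3 against 3 pools the smallest two-sided exact permutation p is 0.1. Total counts were 55.9 to 65.5 M per library, and the biological coefficient of variation was 0.181 for coding genes, 0.312 for long non-coding genes and 1.22 for circular RNAs.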

Results

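RNA was sequenced from adherent peritoneal macrophages of Balb/c mice that had received BSN-37, a compound known here only by its code name, or phosphate-buffered saline (PBS). Each group held 18 mice, pooled by 6 into 3 biological replicates, so that every library stands for a pool of animals. The mice had been primed with thioglycollate, an irritant broth that draws monocytes and macrophages into the peritoneal cavity, and were injected with 0.2 mL of PBS or of BSN-37 at 48 µg/mL 12 h before the cavity was washed out. The cells were left to adhere for 4 h and the medium was replaced, a step that enriches macrophages over non-adherent cells. Total counts over genes were 60.4, 62.2 and 65.5 M in PBS libraries 1 to 3 and 55.9, 60.6 and 64.9 M in BSN-37 libraries 1 to 3. Between 20803 and 21879 genes had at least 1 read per library. Back-splice junctions, the reads that mark circular RNAs, were far fewer, at 2447 to 4564 reads per library. PBS library 1 stood apart from the others on the first principal component of the coding genes, which held 40.4% of the variance (score -37.03, against -1.47 to 15.6 in the other libraries).

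The main comparison asked how the transcriptome of the adherent cells differed after BSN-37, with lavage at 12 h and then 4 h of adherence. The RNA of Zfp36l1, which encodes an RNA-binding protein that promotes decay of AU-rich messages, rose from 4.60 ± 0.681 to 12.9 ± 1.82 FPKM (SD, n = 3 pools per group, as for all FPKM values given here), a log2 change of 1.46 (SE 0.15). The gene lies on chromosome 12 from 80107754 to 80113013, minus strand (GRCm38). No other coding gene passed, and the next on the higher side by p were receptor genes. Ccr2, the receptor that brings monocytes out of the blood, had 24.5 ± 5.19 FPKM in the PBS pools and 55.2 ± 4.83 in the BSN-37 pools (log2 difference 1.14). Ccr1, a receptor of CCL3 and CCL5, had 17.7 ± 4.04 and 39.3 ± 1.39 FPKM (1.12), and Il7r, the interleukin 7 receptor, 6.99 ± 1.64 and 16.4 ± 1.61 (1.20).

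Of 9874 coding genes tested with edgeR, 1 passed the Benjamini-Hochberg threshold, Zfp36l1 (adjusted p = 0.0477). At an unadjusted p under 0.05 there were 900 genes, 465 higher and 435 lower after BSN-37, where chance alone gives 493.7. DESeq2 called 119 genes (81 higher, 38 lower), Zfp36l1 among them (adjusted p = 2.59e-14), and limma on log2 FPKM called 0, with 868 genes at an unadjusted p under 0.05. The groups did not overlap for 1442 genes (14.6%, where chance gives 10%). By the threshold in the design text, an unadjusted p under 0.05 with a mean ratio above 2, 72 genes qualified, 64 of them higher in the BSN-37 pools. Zfp36l1 passed in 1 of the 6 refits with a library left out, that without BSN-37 library 2 (adjusted p = 0.0245), and in the other 5 its adjusted p lay between 0.0853 and 0.402 with log2 changes of 1.36 to 1.55. Of 10 other settings it passed in 3. Those without the call included edgeR at 5 FPKM or more (adjusted p = 0.0511), with median-of-ratios scaling (0.0566) and with a replicate block (0.118).

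**Figure D1:**
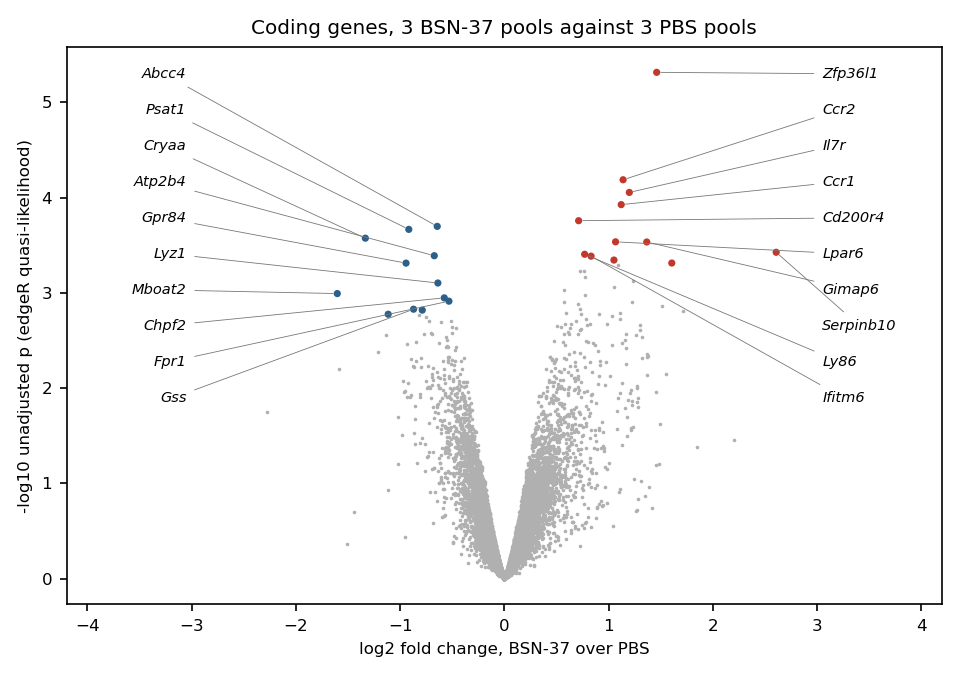
Coding genes by log2 fold change (BSN-37 over PBS, x axis) and -log10 of the unadjusted edgeR p (y axis). Coloured points are the genes of lowest p in each direction, 20 of them named, and the highest point is Zfp36l1, the only gene past the adjusted threshold.

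The other genes of lowest p on the higher side each had an adjusted p of 0.278. Cd200r4, an activating receptor of myeloid cells, had 8.65 ± 0.214 FPKM in the PBS pools and 14.1 ± 1.22 in the BSN-37 pools. Ly86, the partner of the Toll-like receptor homologue CD180, had 15.5 ± 1.96 and 26.9 ± 1.77. Gpr65, an acid-sensing receptor, had 3.35 ± 0.544 and 7.07 ± 1.33, and Lpar6, a lysophosphatidic acid receptor, 2.67 ± 0.618 and 5.73 ± 0.984. Serpinb10, a serine protease inhibitor of the ovalbumin family, showed the widest gap of the named genes, at 0.921 ± 0.547 and 7.78 ± 2.87 FPKM (log2 difference 2.61, SE 0.46). Gimap6, a GTPase of lymphocytes, stood at 0.497 ± 0.0711 and 1.44 ± 0.190.

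On the lower side no gene passed with edgeR. Abcc4, an exporter of cyclic nucleotides and prostaglandins, had 15.8 ± 0.365 FPKM in the PBS pools and 10.3 ± 0.188 in the BSN-37 pools (log2 difference -0.64, adjusted p = 0.278). Psat1, an enzyme of serine synthesis, had 23.6 ± 4.07 and 12.9 ± 0.438 (-0.92), and Gss, which completes glutathione synthesis, 39.4 ± 6.72 and 22.1 ± 4.46 (-0.87). Gpr84, a receptor of medium-chain fatty acids, had 53.8 ± 10.5 and 28.5 ± 2.90 (-0.94). Fpr1, the formyl peptide receptor, had 167 ± 11.9 and 118 ± 10.7 (-0.53), and Lyz1, a lysozyme, 728 ± 100.2 and 476 ± 24.1 (-0.64). Lyz1 has a close paralog, and how reads shared between them were counted is not given in the sources used here. Cryaa, the lens chaperone alpha-A crystallin, had 22.3 ± 7.27 and 8.98 ± 0.868 (-1.33), Atp2b4, a calcium pump, 12.1 ± 0.367 and 7.64 ± 0.622 (-0.67), and Mboat2, a lysophospholipid acyltransferase, 2.64 ± 0.909 and 0.891 ± 0.299 (-1.60). Chpf2 (44.3 ± 5.60 and 28.2 ± 3.50 FPKM), Tsku (8.74 ± 0.929 and 5.09 ± 0.942) and Wnt6 (2.01 ± 0.576 and 0.965 ± 0.122) completed the 12 genes of lowest p.

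**Figure D2:**
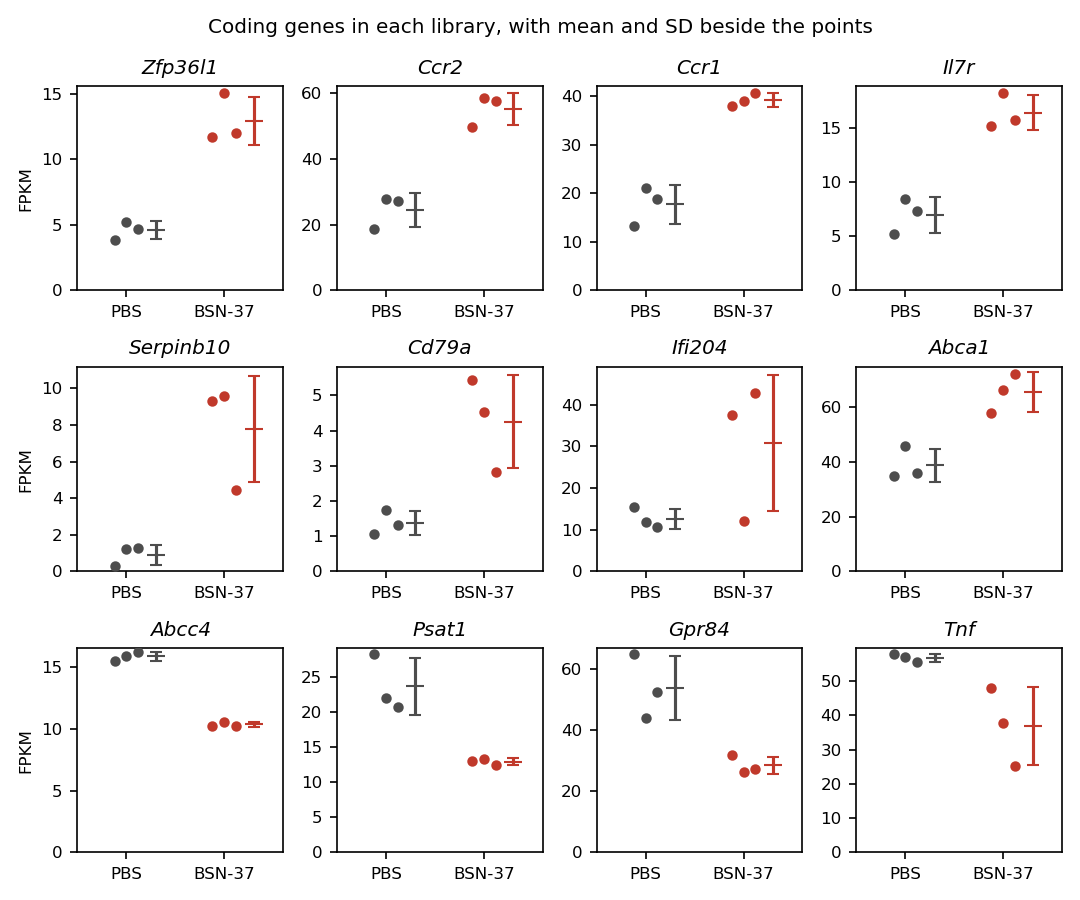
FPKM of 12 coding genes in each library (points, PBS in grey and BSN-37 in red), with the group mean and SD beside the points. Zfp36l1 lies at 4.60 ± 0.681 in PBS and 12.9 ± 1.82 in BSN-37, while Ifi204 in BSN-37 library 2 sits at 12.2, near the PBS libraries.

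Markers of monocytes and of macrophages derived from them stood higher in the BSN-37 pools. Of 18 measured members, 14 were higher, and the list had a median log2 difference of 0.34 (camera adjusted p = 0.000108). With an estimated correlation the adjusted p was 0.546, and with a library left out the median ranged from 0.22 to 0.44, called each time. No member passed over all genes tested, and 4 passed when adjusted over the list alone, all higher: Ccr2, Ifitm6, Ly6c2 and Vcan. Ifitm6, an interferon-induced transmembrane protein of myeloid cells, had 18.5 ± 2.28 FPKM in PBS and 33.8 ± 4.68 in BSN-37. Ly6c2, which marks inflammatory monocytes, had 6.26 ± 0.788 and 19.1 ± 9.33, and the proteoglycan gene Vcan 48.4 ± 20.96 and 114 ± 45.2. The level of this list did not overlap between the groups (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 pools allow).

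Genes of B cells, lymphocytes that live in the peritoneal cavity beside macrophages, stood higher after BSN-37. All 10 measured members were higher, with a median log2 difference of 1.09 (camera adjusted p = 2.65e-11, adjusted p = 0.538 with an estimated correlation). None passed over all genes, and 6 passed when adjusted over the list alone. Cd79a, part of the B cell receptor, had 1.37 ± 0.343 and 4.25 ± 1.32 FPKM, and Ms4a1, the gene of CD20, 0.898 ± 0.464 and 2.72 ± 1.54. The immunoglobulin genes Igkc (17.7 ± 4.68 and 40.4 ± 15.98) and Ighm (10.7 ± 3.48 and 22.1 ± 7.95) were the most abundant of the named members. The list's level was -0.11, 0.59 and -0.59 in PBS libraries 1 to 3 and 1.46, 1.40 and 0.34 in BSN-37 libraries 1 to 3, in log2 units relative to the PBS mean of each gene, so that BSN-37 library 3 lay below PBS library 2 (exact permutation p = 0.2).

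Interferon-stimulated genes, the antiviral set switched on by type I interferon, stood higher on average, with a wide spread between pools. Of 44 measured members 41 were higher, with a median log2 difference of 0.46 (camera adjusted p = 0.000233, adjusted p = 0.755 with an estimated correlation). None passed over all genes and 0 passed in edgeR when adjusted over the list alone, with 3 at an unadjusted p under 0.05 and 0 called by DESeq2. Ifi204, a nucleic acid sensor, had 12.6 ± 2.46 FPKM in PBS and 30.8 ± 16.3 in BSN-37, and the guanylate-binding protein gene Gbp7 2.20 ± 0.595 and 4.29 ± 2.04. Ifi205 had 1.31 ± 0.115 and 3.02 ± 1.44, and Slfn5, of the schlafen family, 33.9 ± 10.5 and 60.9 ± 34.2. The list's level was 0.62, -0.26 and -0.32 in the PBS libraries and 0.82, -0.76 and 1.00 in the BSN-37 libraries, so that the lowest and the highest values were both of the BSN-37 group (exact permutation p = 0.8). The call was lost without PBS library 3 (median 0.28, adjusted p = 0.161), without BSN-37 library 1 (0.28, 0.174) and without BSN-37 library 3 (0.17, 0.418), and the median was 0.85 without BSN-37 library 2 and 0.84 without PBS library 1.

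Resident peritoneal macrophage markers had a median log2 difference of 0.47 (camera adjusted p = 0.00269, adjusted p = 0.606 with an estimated correlation), with 14 of 19 measured members higher. Its level was -0.11 in BSN-37 library 3, below every PBS library (-0.10 to 0.12), and 0.59 and 0.61 in BSN-37 libraries 1 and 2 (exact permutation p = 0.4). Its members went both ways. None passed over all genes, while Apoc1, an apolipoprotein, was higher (0.494 ± 0.109 and 1.36 ± 0.274 FPKM) and Lyz1 lower when adjusted over the list alone. Naip1, an inflammasome sensor, had 4.82 ± 0.897 and 7.02 ± 0.215, and the coagulation factor gene F5 4.96 ± 0.271 and 7.64 ± 2.46. The call was lost without BSN-37 library 1 (median 0.37, adjusted p = 0.0693) and without BSN-37 library 2 (0.29, 0.0946). General macrophage identity genes shifted less, with a median of 0.10 and 14 of 20 higher (camera adjusted p = 0.0287, adjusted p = 0.606 with an estimated correlation). Of these, 2 passed when adjusted over the list alone and 0 over all genes: Aif1, which encodes the calcium-binding protein IBA1 (5.82 ± 0.588 and 10.4 ± 2.11), and the transcription factor gene Cebpb (13.3 ± 4.78 and 30.1 ± 9.60). The main macrophage receptors differed little, at 379 ± 48.9 and 324 ± 63.6 FPKM for Adgre1 (the gene of F4/80) and 449 ± 57.6 and 445 ± 46.5 for Csf1r, and the identity call was lost without PBS library 2 (median 0.07, adjusted p = 0.248) and without BSN-37 library 1 (0.05, 0.111), and with limma at a pseudocount of 1 (adjusted p = 0.0610) or 0.1 (0.0609).

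Genes for uptake and lipid handling stood higher after BSN-37. Of 32 phagocytic and scavenger receptors 24 were higher, with a median log2 difference of 0.22 (camera adjusted p = 0.00122, adjusted p = 0.416 with an estimated correlation). Clec7a, the beta-glucan receptor Dectin-1, had 28.3 ± 6.03 FPKM in PBS and 62.6 ± 20.1 in BSN-37, and the phosphatidylserine-binding receptor gene Cd300lf 12.0 ± 2.64 and 27.0 ± 10.2. These 2 passed when adjusted over the list alone, and 0 of the 32 passed over all genes. The median ranged from 0.14 to 0.24 with a library left out, called each time. Of 24 genes of lipid handling or controlled by the nuclear receptors LXR and PPAR, 14 were higher (median 0.09, camera adjusted p = 0.0122, adjusted p = 0.538 with an estimated correlation). Adjusted over the list alone 5 passed, all higher, and over all genes 0. They included Abca1, the cholesterol exporter (38.9 ± 6.07 and 65.5 ± 7.28), Pparg, the gene of PPAR gamma (7.01 ± 0.604 and 10.8 ± 1.51), Gpnmb, a glycoprotein of lysosome-rich macrophages (11.4 ± 2.27 and 21.6 ± 4.64), and the fatty acid binding protein gene Fabp5 (5.62 ± 0.999 and 11.1 ± 4.32). The lipid list lost its call without PBS library 2 (median 0.10, adjusted p = 0.0711) and without PBS library 3 (0.06, 0.114). It was called in 4 of 11 other settings, and not with no filter (adjusted p = 0.0601), at 5 FPKM or more (0.0896), with fry (0.160) or with limma at a pseudocount of 1 (0.0997) or 0.1 (0.0945) or after quantile normalization (0.0754).

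For the activation state of the macrophages, inflammatory mediators and genes of alternative activation were compared. Arg1, the arginase of alternatively activated macrophages, had 125 ± 25.8 FPKM in PBS and 187 ± 19.4 in BSN-37 (log2 difference 0.56, adjusted p = 0.426). Mrc1, the mannose receptor gene, went the other way at 8.63 ± 1.32 and 6.42 ± 1.12 (-0.47, adjusted p = 0.506). Tnf had 56.8 ± 1.16 and 36.9 ± 11.4 (-0.65, adjusted p = 0.449), Il1b 34.6 ± 16.3 and 44.0 ± 28.3 (0.30), and the costimulatory gene Cd86 19.4 ± 3.37 and 23.7 ± 4.55 (0.24). Nos2 (0.0968 ± 0.0466 and 0.0694 ± 0.0410), Il6 (0.324 ± 0.287 and 0.190 ± 0.128) and Il10 (0.205 ± 0.111 and 0.202 ± 0.0498) lay under the expression filter and were not tested.

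None of the 5 lists of activation and defence described here was called by camera. Proinflammatory mediators had a median log2 difference of -0.07 over 14 genes (adjusted p = 0.434) with 0 members passing over all genes or over the list alone in edgeR, 5 at an unadjusted p under 0.05 and 0 called by DESeq2. Its members of lowest p were Tnf, given above, Ptges, the prostaglandin E synthase gene (123 ± 32.3 and 80.9 ± 5.18 FPKM), Acod1, which makes itaconate (234 ± 12.4 and 160 ± 33.0), and Il18 (5.58 ± 1.05 and 8.48 ± 0.915). Chemokines had a median of -0.08 over 19 genes (adjusted p = 0.312), again with 0 passing in edgeR by either adjustment, 3 at an unadjusted p under 0.05 and 0 called by DESeq2. Cxcl3, a neutrophil attractant, had 35.2 ± 9.43 and 17.6 ± 8.40, Ccl3 13.8 ± 3.85 and 8.51 ± 2.17, and Ccl9 214 ± 4.13 and 286 ± 53.2. In the list of pattern recognition and NF-kB genes (39 measured, median -0.10, adjusted p = 0.190), 6 members passed when adjusted over the list alone, 2 higher and 4 lower, and 0 over all genes. The nucleic acid sensors Tlr7 (22.7 ± 4.31 and 40.1 ± 4.55) and Tlr8 (17.1 ± 3.04 and 29.0 ± 4.59) were higher, and Traf1 (29.2 ± 4.15 and 19.9 ± 2.04) and the inhibitor gene Nfkbia (162 ± 22.2 and 114 ± 12.4), both NF-kB targets, were lower. In the alternative activation list (28 measured, median 0.03, adjusted p = 0.408), Pparg and Clec7a passed when adjusted over the list alone and 0 over all genes, and Vegfa had 1.33 ± 0.307 and 2.22 ± 0.232. Complement and coagulation genes (25 measured, median 0.06, adjusted p = 0.312) held 1 that passed over the list alone and 0 over all genes, the matrix protein gene Thbs1 (26.8 ± 3.75 and 90.5 ± 57.6), followed by Serpinb2, a plasminogen activator inhibitor (43.3 ± 21.8 and 108 ± 46.9).

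Adhesion and matrix genes also went both ways (23 measured, median 0.01, mean 0.21, camera adjusted p = 0.190). Over the list alone 5 passed and over all genes 0. Besides Thbs1, the integrin genes Itga6 (28.0 ± 6.18 and 48.0 ± 8.16 FPKM) and Itga4 (23.7 ± 4.84 and 33.7 ± 0.842) were higher, and the adhesion receptor gene Icam1 (70.5 ± 12.6 and 49.0 ± 1.63) was lower. Neutrophil markers (13 measured) had a median of 0.26 (camera adjusted p = 0.312) with 8 higher and 0 passing in edgeR by either adjustment, 2 at an unadjusted p under 0.05 and 1 called by DESeq2. Csf3r, the receptor of granulocyte colony-stimulating factor, had 58.3 ± 4.26 and 80.3 ± 8.77, and Mmp8, a neutrophil collagenase, 6.64 ± 3.51 and 18.8 ± 15.6.

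Cell cycle, cholesterol synthesis and oxidant defence genes stood lower after BSN-37. Of 28 cell cycle genes 25 were lower (median log2 difference -0.31, camera adjusted p = 9.10e-05, adjusted p = 0.606 with an estimated correlation). The cell cycle level was -0.66 in BSN-37 library 3 and -0.25 in library 1, while library 2 (0.01) lay within the PBS range of -0.10 to 0.08 (exact permutation p = 0.3). Uhrf1, a factor of DNA methylation maintenance, had 2.09 ± 0.443 and 1.40 ± 0.344 FPKM, and the thymidine kinase gene Tk1 2.50 ± 0.252 and 1.76 ± 0.263. Of 23 cholesterol synthesis genes 19 were lower (median -0.23, camera adjusted p = 0.000472, adjusted p = 0.606 with an estimated correlation), with Hsd17b7 at 3.42 ± 0.491 and 2.35 ± 0.503 and Sqle, the squalene epoxidase gene, at 9.05 ± 1.89 and 6.96 ± 0.531. Of 26 genes of the NADPH oxidase and oxidant defence 20 were lower (median -0.19, camera adjusted p = 0.00266, adjusted p = 0.606 with an estimated correlation). Hmox1, which degrades heme, had 2058 ± 191 and 1301 ± 238, the thioredoxin reductase gene Txnrd1 218 ± 9.59 and 165 ± 29.1, and Sod2, the mitochondrial superoxide dismutase gene, 129 ± 5.85 and 106 ± 1.01. In these 3 lists 0 members passed in edgeR over all genes or over the list alone, with 4, 4 and 7 lower at an unadjusted p under 0.05, and DESeq2 called 0, 0 and 1. The call was lost for cholesterol synthesis without PBS library 1 (median -0.08, adjusted p = 0.0607) and for oxidant defence without PBS library 3 (-0.11, 0.182) and without BSN-37 library 3 (-0.10, 0.104), while the cell cycle call held each time with medians of -0.45 to -0.12. Among genes of at least 5 FPKM the cell cycle median was -0.03 (adjusted p = 0.441).

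**Figure D3:**
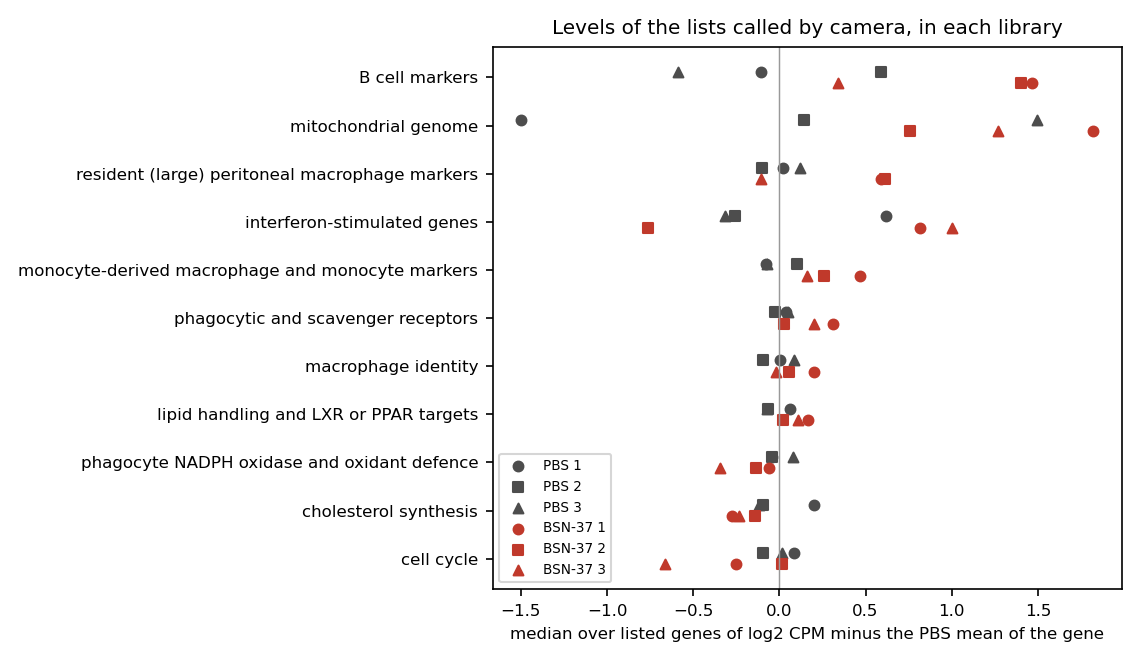
Level of the 11 lists called by camera in each library (marker shapes for libraries 1 to 3, PBS in grey, BSN-37 in red), as the median over listed genes of log2 CPM minus the PBS mean of the gene. The interferon-stimulated genes span -0.76 to 1.00 within the BSN-37 group, and the mitochondrial genome list spans -1.50 to 1.50 within PBS.

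The 13 genes of the mitochondrial genome were all higher in the BSN-37 pools (median log2 difference 0.77, camera adjusted p = 9.10e-05, adjusted p = 0.606 with an estimated correlation). With a library left out the median ranged from 0.34 to 1.83, and the call held each time, while with DESeq2 values camera did not call the list (adjusted p = 0.0563). None passed in edgeR over all genes or over the list alone, 0 had an unadjusted p under 0.05 and DESeq2 called 0. Mitochondrial transcripts took 0.260% of counts in PBS library 1, 0.597% and 1.00% in PBS libraries 2 and 3, and 1.02%, 0.665% and 0.677% in the BSN-37 libraries (exact permutation p = 0.4). The mt-Co3 gene, a cytochrome oxidase subunit, had 747 ± 516 and 1303 ± 390 FPKM. PBS library 1 also had the largest share of Gm26917, a transcript that overlaps ribosomal RNA sequence, at 6.06% of counts against 4.07% to 4.44% in the other libraries.

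Across all lists, camera called 11 of 29 tested at the preset correlation, 8 higher and 3 lower. With an estimated correlation it called 0, with 2 lists at an unadjusted p under 0.05. The rotation test fry, which asks whether a set's genes move on balance one way, called 0 with 3 at an unadjusted p under 0.05. In its mixed form, which asks whether members change in either direction, it called 9. Among these were alternative activation (adjusted p = 0.0462), pattern recognition and NF-kB (0.0462) and complement and coagulation (0.0325). Proinflammatory mediators (0.0925) and chemokines (0.127) were not called by the mixed form. The levels of 3 of the 11 called lists did not overlap between the groups, those of monocytes, cholesterol synthesis and oxidant defence (exact permutation p = 0.1 each). For the other 8 the exact permutation p was 0.2 (B cells, lipid handling), 0.3 (phagocytic receptors, cell cycle, mitochondrial genome), 0.4 (resident macrophages), 0.5 (macrophage identity) and 0.8 (interferon-stimulated genes). Of 784 list memberships 0 passed over all genes in edgeR, and 13 lists held members that passed when adjusted over the list alone.

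Long non-coding RNAs were compared in the same way. The transcript Gm37094, on chromosome 14 from 69495851 to 69500390 (minus strand, GRCm38), fell from 3.26 ± 0.795 to 0.889 ± 0.258 FPKM, a log2 change of -1.91 (SE 0.28), and was the only one of 719 tested to pass (adjusted p = 0.0491). DESeq2, applied after the data had been seen, called 3, and limma called 0 with 38 at an unadjusted p under 0.05, where edgeR had 51. Pvt1, a transcript next to Myc, had 2.25 ± 0.00786 FPKM in PBS and 1.35 ± 0.256 in BSN-37 (log2 difference -0.74, adjusted p = 0.554). The antisense transcript H3f3aos had 1.28 ± 0.424 and 0.773 ± 0.0294, and Mirt1 1.42 ± 0.629 and 0.848 ± 0.0145. Ftx, near Xist, had 1.39 ± 0.325 and 1.28 ± 0.151, and the transcript listed as Trmt61b 0.876 ± 0.333 and 0.565 ± 0.0893. On the higher side stood Hm629797 (0.737 ± 0.0701 and 1.05 ± 0.0491), Airn (5.91 ± 1.81 and 8.88 ± 6.15), Tug1 (20.1 ± 4.86 and 26.2 ± 3.13), Bach2os (0.622 ± 0.0536 and 1.03 ± 0.559) and Phtf1os (0.714 ± 0.268 and 0.979 ± 0.113). None of these passed. The abundant nuclear transcripts Malat1 (892 ± 202.7 and 865 ± 104.5) and Neat1 (26.8 ± 4.28 and 34.4 ± 19.2) differed by less than the spread between pools. Of 23 measured members of the list of long non-coding RNAs with immune roles, 0 passed with edgeR over all tested or over the list alone, 2 had an unadjusted p under 0.05 and limma called 0. The Gm37094 call held in 2 of the 6 refits with a library left out, those without PBS library 3 and without BSN-37 library 2, and in the other 4 its adjusted p was 0.138 to 0.380 with log2 changes of -1.71 to -1.89.

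Circular RNAs, made by splicing an exon end back to an upstream exon start, were compared from their back-splice junction reads. The circular RNA of Sfi1, a centrosome protein gene, had 27, 44 and 52 reads in PBS libraries 1 to 3 and 0 in each BSN-37 library. Against a floor of 3 reads over the BSN-37 group it was 39.9-fold higher in PBS (counting error only). It was the only one of 168 circular RNAs tested to pass in edgeR (adjusted p = 0.0418). A 0 can also stand where other libraries have many reads, as for Cacna1d with 180, 133 and 0 in BSN-37 libraries 1 to 3. The 39.9-fold is therefore not a firm lower bound. The circular RNA of Sfi1 spans exons 15 to 22 on chromosome 11 from 3140137 to 3146292 (GRCm38), 841 nt of exon sequence. Of its 31-base words, 22.8% also occur in transcripts of 2 other genes. DESeq2 called 2 circular RNAs, and limma called 0 with 7 at an unadjusted p under 0.05. The Sfi1 call held in 1 of the 6 refits with a library left out, that without BSN-37 library 3 (adjusted p = 0.0431), and in the other 5 the adjusted p was 0.0597 to 0.322.

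In edgeR 5 circular RNAs had an unadjusted p under 0.05, where chance gives 8.4, and all were read in every PBS library and in no BSN-37 library. None was read in every BSN-37 library and no PBS library. Besides Sfi1 these were Papd7, a non-canonical poly(A) polymerase gene, exons 2 to 4 on chromosome 13 from 69512890 to 69515903 (16, 9 and 12 reads), and Dcaf17, exons 2 to 4 on chromosome 2 from 71056495 to 71063495 (19, 8 and 6 reads). Elf2, an ETS factor gene, gave exons 2 to 5 on chromosome 3 from 51299783 to 51326035 (9, 10 and 6 reads). Maml2, a Notch coactivator gene, gave exon 2 on chromosome 9 from 13619990 to 13621675 (8, 2 and 4 reads). In the other direction the lowest p had a junction on chromosome 1, described next, followed by circular RNAs of Arhgap5 (0, 0 and 2 reads in PBS and 3, 5 and 3 in BSN-37), Casc5 (0, 3 and 0; 14, 8 and 0), Erbb2ip (0, 0 and 21; 26, 25 and 22) and Acvr2a (6, 0 and 0; 9, 6 and 16), none of which passed (adjusted p = 0.996).

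Most circular RNAs were seen in few libraries. Of 1273 loci, 977 were read in 1 library and 42 in all 6. The highest total over the 6 libraries had a junction on chromosome 1 from 173912814 to 173982741, with no host gene in the deposited table, which reaches across Ifi211, Ifi203, Mndal and Ifi202b of the interferon-inducible Ifi200 family and has an annotated exon end at only 1 side. It had 102, 122 and 210 reads in PBS and 360, 132 and 342 in BSN-37 (log2 difference 1.00, adjusted p = 0.996). Circular RNAs of Tulp4 (153, 176 and 220 reads in PBS; 155, 153 and 111 in BSN-37) and Ep400 (129, 91 and 151; 147, 128 and 76) were read in all libraries. That of Cacna1d had 51, 122 and 161 reads in PBS, 180 and 133 in BSN-37 libraries 1 and 2, and 0 in BSN-37 library 3. Over 163 circular RNAs the log2 difference went weakly with that of the host gene (Pearson 0.138, bootstrap SD 0.0677; Spearman 0.146), across loci that are not independent replicates, and the value was 0.424 over the 39 read in all 6 libraries. With a library left out it ranged from 0.0135 (without BSN-37 library 2) to 0.233 (without PBS library 3).

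**Figure D4:**
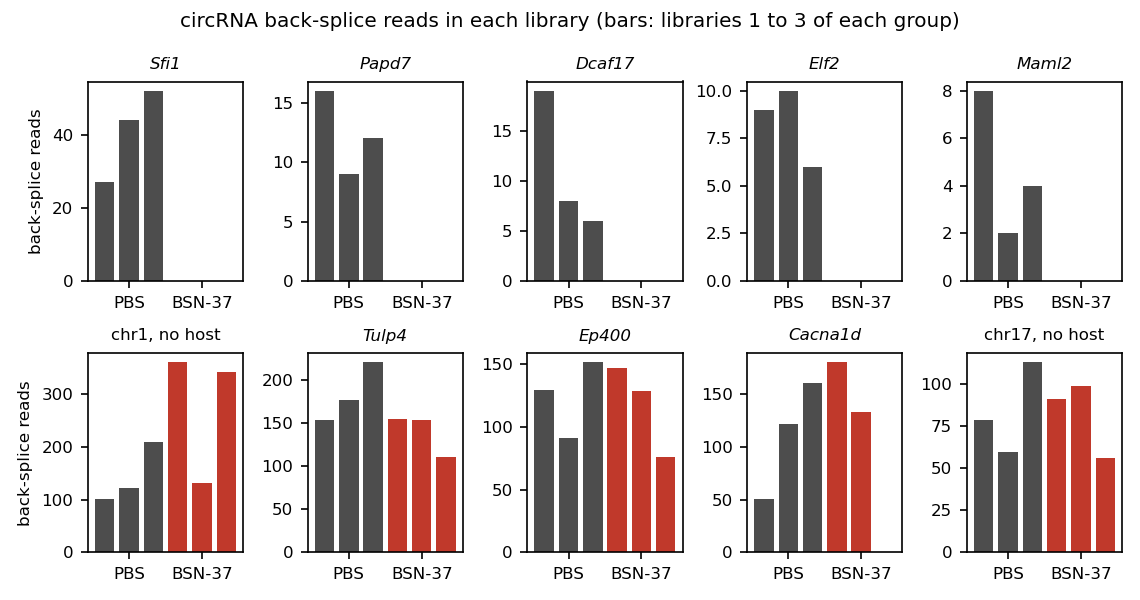
Back-splice reads per library (bars, PBS libraries 1 to 3 in grey, BSN-37 libraries 1 to 3 in red) for the 5 circular RNAs read in every PBS and no BSN-37 library (top) and the 5 with the highest total over the 6 libraries (bottom). Sfi1 has 27, 44 and 52 reads in PBS and 0 in BSN-37, and Cacna1d has 0 in BSN-37 library 3 alone.

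The authors' deposited table gives its own DESeq2 comparison. At p under 0.05 and 1.5-fold it calls 104 genes of all classes higher and 45 lower after BSN-37, of which 89 and 31 are coding. At 2-fold it calls 6 circular RNAs higher and 14 lower. These rules differ from those of the edgeR counts above. Of those 20 circular RNAs, 16 were read in 1 or 2 libraries. For Zfp36l1 the authors' deposited table lists a log2 change of 1.25, and for Ccr2 0.97, smaller than the edgeR values of 1.46 and 1.14. Over 9845 coding genes its log2 changes correlated with those of edgeR at 0.963 (Pearson, across genes), with the same sign for 99.6%, both being computed from the same counts.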

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

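DESeq2 and the TMM factors of the coding genes were chosen for the long non-coding genes after the data were seen; the other alternatives were planned before the data were examined. Testing per transcript was not run, since the deposited table is per gene. The number of coding genes past the adjusted threshold (1 with edgeR) was 2 with no filter, 0 with a filter of 5 FPKM, 0 with median-of-ratios scaling, 119 with DESeq2, 25 with limma array weights and 0 with limma at a pseudocount of 1 or 0.1, after quantile normalization or without trend; it ranged from 0 to 12 with a library left out, the 12 being without BSN-37 library 2, where Zfp36l1 remained and 11 genes joined it, of which Ifi204 is on the interferon list. The cause of these differences between tools was not tested. The count by the threshold of the design text (72, of which 64 higher and 8 lower) was 232 with no filter (169 higher and 63 lower) and 33 with a filter of 5 FPKM (31 and 2), for which the number of genes tested, 15580 and 6988, is part of the cause. With a library left out it was 69 to 125, highest without PBS library 3. Lists called (11) were 17 with array weights, 0 with an estimated correlation and 0 with fry, and 8 to 14 with a library left out. Long non-coding genes called (1) were 0 with limma at either pseudocount, 11 with no filter, 2 with a filter of 1 FPKM, 3 with DESeq2, 0 with the coding factors and 0 to 3 with a library left out, the 3 being without BSN-37 library 2. Circular RNAs called (1) were 2 with no filter, 0 among those read in all 6 libraries, 0 scaled to total circular reads, 2 with DESeq2, 0 with limma with 1 read or less added and 0 to 2 with a library left out, the 2 being without BSN-37 library 3. By the threshold of the design text (5) they were 19 with no filter, 1 among those read in all 6 libraries and 3 to 7 with a library left out, lowest without PBS library 2. The filter of reads in all 6 libraries removes by construction every circular RNA with 0 reads in BSN-37, Sfi1 among them. The correlation of circular RNAs with host genes (0.138) was 0.424 over those read in all 6 libraries, 0.219 with 5 reads added and 0.0135 to 0.233 with a library left out, lowest without BSN-37 library 2 and highest without PBS library 3. The replicate numbers share only a number: with the number as a replicate block 0 coding and 0 long non-coding genes and 1 circular RNA were called. After each group's mean was subtracted per gene, the deviations of same-numbered libraries correlated at 0.0548, 0.148 and 0.00143. By these deviations only number 2 correlated best with its own. Signs turned for values that were never called: Csf1r (0.00343 after quantile normalization, 0.0647 with array weights, 0.0699 without PBS library 1, 0.00291 without BSN-37 library 3; with a library left out -0.12 to 0.0699), Il1b (-0.135 with array weights, -0.223 without BSN-37 library 2, the lowest, against 0.71 without PBS library 2), Gm26917 (0.123 without PBS library 1, -0.32 without PBS library 2), Malat1 (0.00797 without PBS library 3, -0.19 without PBS library 1) and Neat1 (-0.176 without BSN-37 library 3, 0.44 without BSN-37 library 2), and the cause was not tested. Of all values, these among them, 1394 of 1472 for the 93 named coding genes and 143 of 186 for the 11 called lists kept direction and side of the threshold, and the remaining list values (43) lost the call without turning. The 10 named circular RNAs kept both in 122 of 131 values and the 14 long non-coding RNAs in 181 of 192. Outside the lists these shares mostly count members called neither in the main fit nor in the alternative, and so do not measure how well calls held. Zfp36l1 was called in 1 of 6 refits with a library left out and in 3 of 10 other settings. Gm37094 was called in 2 of 6 and 4 of 8, and the circular RNA of Sfi1 in 1 of 6 and 4 of 7. Scaling moved the median of the coding genes to between -0.0233 and 0.0212 (log2).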

Other observations

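The tests on B cell markers, interferon-stimulated genes and detection of circular RNAs, the KEGG pathways and the genes named in this part were chosen after the results had been seen, while the splits of the libraries and the search for shared sequence were set beforehand. Other groups of genes stood as follows. Of 30 glycolysis and hypoxia genes 23 were lower (median log2 difference -0.11, camera adjusted p = 0.0993), with the glucose transporter gene Slc2a1 at 74.3 ± 1.72 and 50.9 ± 10.5 FPKM in PBS and BSN-37. Lysosome genes (39 measured, median 0.01, adjusted p = 0.190) included the cathepsin gene Ctsl at 617 ± 19.2 and 808 ± 100.2. In the list of apoptosis and p53 targets (23 measured, median 0.10, adjusted p = 0.190) the survival gene Bcl2a1b passed when adjusted over the list alone (13.6 ± 2.50 and 22.9 ± 0.235) and none over all genes. Of the 3 measured eosinophil markers, Adgre4, also a macrophage gene, had 27.8 ± 6.22 and 53.7 ± 20.99. The heat shock genes Hspa1b (17.7 ± 1.28 and 12.5 ± 1.30) and Hspa1a were lower in value in a list of chaperones whose median was 0.03 (adjusted p = 0.571). Antigen presentation by MHC class I (median 0.10, adjusted p = 0.166) and class II (0.03, 0.611), nuclear oxidative phosphorylation genes (0.01, 0.796), ribosomal protein genes (0.05, 0.553), histone genes (-0.08, 0.0748), immediate early genes (-0.02, 0.838) and dendritic cell markers (-0.18, 0.553) were not called by camera. Lists with too few measured members were those of T and NK cells (Il7r alone), eosinophils (3), mast cells and basophils (1), mesothelium and fibroblasts (4), erythroid cells and platelets (2) and gut epithelium (0).

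Of 230 KEGG pathways of the deposited annotation with 10 to 300 tested genes, most disease pathways left out, camera called 5. With an estimated correlation it called 0 (adjusted p = 0.932), with 5 at an unadjusted p under 0.05, fewer than chance alone gives. Of the called pathways only cysteine and methionine metabolism was among those (camera p = 0.0310 with an estimated correlation). The other called pathways had 0.0705 to 0.191. Biosynthesis of amino acids had 36 of 49 genes lower (median log2 difference -0.13), carbon metabolism 63 of 87 (-0.10), and cysteine and methionine metabolism 25 of 34 (-0.15). Of the serine synthesis enzymes, Phgdh had 8.95 ± 1.73 FPKM in PBS and 6.87 ± 0.837 in BSN-37 (adjusted p = 0.543), and Psat1 is given in the report. Adipocytokine signalling was also lower (-0.09) and the hematopoietic cell lineage pathway higher (33 of 47 genes, 0.13). Gm42418, a long non-coding transcript that overlaps ribosomal RNA sequence, had 3003 ± 2769 and 461 ± 522 FPKM (log2 difference -2.76) and took 0.704%, 0.0261% and 1.25% of counts in PBS libraries 1 to 3 against 0.0364%, 0.227% and 0.0341% in the BSN-37 libraries.

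Markers of B cells were higher in the BSN-37 pools. A smaller share of macrophages would lift markers of all minor cell types alike. The B cell markers exceeded 50 low-level markers of other cell types by 0.75 in median log2 difference (bootstrap SD over genes 0.17). Of those 50, 36 were also higher (median 0.26). That SD treats genes as independent and leaves out the spread between pools, where the B cell level overlapped between groups (exact permutation p = 0.2). The test therefore cannot set this explanation aside. A larger share of B cells may account for the pattern: the 10 measured markers varied together within groups (mean correlation 0.75, above all 1000 random lists, percentile 100), and 15 of 15 markers at any level were higher. The random lists were matched for expression level only, so other genes regulated together could also exceed them. The test therefore does not separate a share of B cells from another shared cause. None of the listed markers belongs to another list, and how many of them macrophages express was not tested. The most abundant, Igkc and Ighm, reached 40.4 and 22.1 FPKM after the adherence step. How far that step removed lymphocytes from these pools was not measured. Whether BSN-37 raised the number of B cells, the pools differed in how many were carried over, or another shared cause acted stays open.

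Interferon-stimulated genes were higher on average in the BSN-37 pools. PBS library 1, which stands apart in all genes, does not account for it. Its list level was the highest of the PBS libraries (0.62 against -0.26 and -0.32), near the 0.82 of BSN-37 library 1. Leaving it out was therefore bound to raise the median difference, which was 0.84 without it and 0.46 with it. A level of 0.62 without BSN-37 also shows that pools can differ by this much untreated. Variation between pools whatever their treatment and an effect of BSN-37 that library 2 lacks both stay open, since these values do not separate them. Without that library 12 coding genes passed, among them Ifi202b (16.3, 19.6 and 24.0 FPKM in PBS; 55.9, 22.8 and 77.9 in BSN-37), Ifi203, Ifi204, Ifi207, Ifi209, Ifi211 and Mndal of the chromosome 1 cluster. The junction across this cluster was likewise lowest among the BSN-37 libraries in library 2. In PBS library 1 the named cluster genes lay below BSN-37 libraries 1 and 3, with Mndal at 13.1 against 36.5 and 44.4 FPKM.

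The 5 circular RNAs read in all PBS and no BSN-37 libraries were weighed against 3 technical explanations. Fewer circular RNA reads in the BSN-37 libraries are argued against by the ratio of circular reads per gene count, BSN-37 over PBS, 0.994. For sequence shared with other genes, 0 loci had most of their exon words in annotated transcripts of other genes. The share was 22.8% for Sfi1, 6.98% for Maml2 (in 170 other genes) and 0% for Papd7, Dcaf17 and Elf2. The search did not cover the back-splice junction itself, so it cannot set aside shared sequence there. Detection that varies between libraries whatever their group may account for them: the other 9 splits of the libraries gave 3 to 9 such loci (median 6), and 5 of them at least as many as the real one. A model with 1 dropout rate for all loci, computed earlier, expected 0.939 loci (rate 23.2%), but it was set aside because loci differ in dropout, and the splits show more such loci than it allows. Sfi1 had the most of these reads, 123 in PBS. Where both other libraries of the group had at least 20 reads, 14 of 176 values (7.95%) were 0. That share is also pooled over loci and does not cover a group with 0 in every library. It therefore cannot say how easily Sfi1 is missed. For Sfi1 an effect of BSN-37 and detection that varies between libraries both stay open.

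The 6 libraries can be split into 3 and 3 in only 10 ways, too few for a share under 0.05. The real split and the highest of the others gave 1 and 28 coding genes past the adjusted threshold, 72 and 86 by the threshold of the design text, 11 and 15 lists, 1 and 1 long non-coding genes, 1 and 1 circular RNAs, and 5 and 10 circular RNAs by the threshold of the design text. Counting the real one, 5, 2, 6, 3, 2 and 7 of the 10 splits gave as many. The highest coding and list values all came from the split that joins PBS library 1 with BSN-37 libraries 1 and 3, the 3 libraries with the highest interferon levels, which points to a structure of the samples. That split was singled out for its count and holds 2 BSN-37 libraries, so it does not separate variation between pools from an effect that BSN-37 library 2 lacks. At an unadjusted p under 0.05 the real split had 900 coding genes and the others 187 to 454. That count was not among those set beforehand. The other splits mix both groups on each side, so a group difference would widen the spread within their sides, and they are no null. Being the highest of 10 splits cannot give a share under 0.05.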
